A study of Mus musculus with 12 samples.

How the data were processed

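RNA was measured in V6.5 mouse embryonic stem cells, an established line, and in neurons made from them, both carrying MeCP2-GFP as WT or R168X. Per the labels' protocols the stem cells grew without serum in 2i/LIF, a medium that keeps them in the naive state. Neurons came from a doxycycline-inducible NGN2 construct, brought in with PiggyBac, that was switched on with 2 µg/mL doxycycline on a layer of mouse astrocytes, and were collected after 5 days. RNA came from aliquots of 2 M cells, ERCC spike-ins were added in a fixed amount, and ribosomal RNA was depleted. Groups were taken from the labels. The 12 libraries formed 4 groups of 3.

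The deposited count tables hold expected counts per gene symbol, not normalized, for 24954 mouse genes and 92 ERCC spike-ins, per the file headers and values. Tools named in the submitters' processing notes, without role or order, are STAR 2.6.1a, RSEM 1.2.31 and DESeq2 1.24.0, with the genome build mm9. The authors' deposited comparison tables give, per the file headers, a mean normalized signal per gene (baseMean), a log2 fold change of WT over R168X with its standard error, a Wald score, a p-value and an adjusted p-value. The sign is turned here, so that positive means higher in R168X. Size factors recovered from the authors' deposited baseMean differed by at most 0.630% in ESCs and 1.15% in neurons from ERCC size factors computed here.

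Expected counts were rounded to whole numbers. Low genes were removed with filterByExpr, and groups were compared with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. An adjusted p of a gene comes from this test unless another is named. On the spike-in scale the libraries were scaled by DESeq2 1.42.0 median-of-ratios size factors over the ERCC spike-ins with at least 10 counts in every library, 56 in ESCs and 54 in neurons. The spike-in scale follows RNA per counted cell if the aliquots and the added spike-in were equal. On the relative scale the libraries were scaled by TMM over mouse genes, which centres the typical gene. ESCs and neurons were fitted apart. The difference of genotype effects and the comparison of WT neurons with WT ESCs used all 12 libraries, the latter with TMM. SE stands for the standard error of a log2 fold change.

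Tests, alternatives, the rule for named genes and the 28 gene lists were fixed before the data were examined, apart from those the closing part names as chosen later. The lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Named genes were Mecp2 and up to 12 genes per direction with the largest spike-in log2 fold change. These had to pass the threshold on both scales with the same sign, have a mean CPM of at least 1 and show no overlap between the libraries of the genotypes, which chance alone gives in 10% of genes at 3 against 3. Added were up to 4 members per list, those past the threshold on the spike-in scale with the largest change or otherwise the most abundant, 5 genes per direction for the difference of effects, and the 4 most abundant markers per list for cell identity. A fold against a group at 0 counts used a floor of 3 counts over that group. Counting intervals are exact 95% binomial (Clopper-Pearson) intervals, and floors and intervals cover counting error only.

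Gene spans, lengths and chromosomes came from a RefSeq gene table of GRCm38, which is not the build of the files, so no coordinates are given. On simulated counts for 13244 ESC genes the test recovered 79.1% of 1.5-fold and 97.0% of 2-fold changes, and for 13737 neuron genes 79.1% and 97.0%. The difference of effects was recovered for 47.8% of 1.5-fold and 94.0% of 2-fold changes among 14703 genes. The simulation had no global shift and no spread of spike-ins. No pair of libraries of a group agreed within sampling noise, the lowest chi-square per gene being 2.27. Alternatives were other scalings, DESeq2, no filter, a replicate block, a fit of all libraries and leaving out each library in turn. Whether the libraries of a group came from separate cultures is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical. The labels give no batch that crosses genotype, so genotype cannot be told apart from line or preparation, nor cell type from preparation set.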

Results

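Total RNA was sequenced from mouse embryonic stem cells (ESCs) and from neurons derived from them, each carrying MeCP2-GFP that was wild type (WT) or R168X. MeCP2 is a protein that binds methylated DNA, and R168X is a nonsense change of it known from Rett syndrome. Each of the 4 groups had 3 libraries. Total counts were 19.3 to 29.7 M per ESC library and 13.3 to 21.8 M per neuron library, where M stands for 1e6. ERCC spike-ins took 1.94 to 2.51% of the counts in ESCs and 2.68 to 4.65% in neurons.

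Mecp2, the altered gene, was read in every library. Its level was 18.5, 20.8 and 19.6 counts per 1e6 mouse counts (CPM) in the WT ESC libraries and 24.8, 21.3 and 24.8 CPM in the R168X ESC libraries. WT neuron libraries held 91.0, 88.1 and 83.9 CPM and R168X neuron libraries 125, 110.2 and 83.6 CPM. On the spike-in scale the log2 fold change of R168X over WT was -0.05 ± 0.11 in ESCs (edgeR adjusted p = 0.702) and -0.11 ± 0.27 in neurons (edgeR adjusted p = 0.767), neither past the threshold. Relative to the other genes it was 0.23 ± 0.08 in ESCs (edgeR adjusted p = 0.275) and 0.19 ± 0.14 in neurons (edgeR adjusted p = 0.315). A count per gene cannot read a nonsense change, so these values do not check the genotype labels.

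R168X libraries held less mouse RNA per spike-in than WT libraries in both cell types. The spike-ins were added in a fixed amount to compare RNA per cell. Mouse counts per ERCC count were 49.7 ± 0.716 in WT and 41.4 ± 2.21 in R168X ESCs (mean ± SD, n = 3), a change of -16.9%. In neurons they were 35.1 ± 1.10 and 25.03 ± 5.41, a change of -28.7%. Each R168X library lay below each WT library of its cell type, and the exact two-sided permutation p was 0.1 in both, the smallest that 3 against 3 allows. The share of Rn45s, the precursor of ribosomal RNA, was also lower, at 9.06 ± 0.980% in WT and 6.69 ± 0.770% in R168X ESCs and at 13.3 ± 1.04% and 8.90 ± 0.926% in neurons (exact two-sided permutation p = 0.1 in each). The labels state ribosomal RNA depletion, so this share also reads how far depletion went. Without Rn45s the changes in mouse counts per ERCC count were -14.7% and -25.1%. The median gene changed by -0.29 in ESCs and -0.35 in neurons on the log2 spike-in scale, and by -0.23 in neurons without R168X replicate 3. Changes of single genes and groups are therefore given relative to the other genes (TMM scaling) as log2 fold change of R168X over WT ± SE unless the spike-in scale is named.

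**Figure D1:**
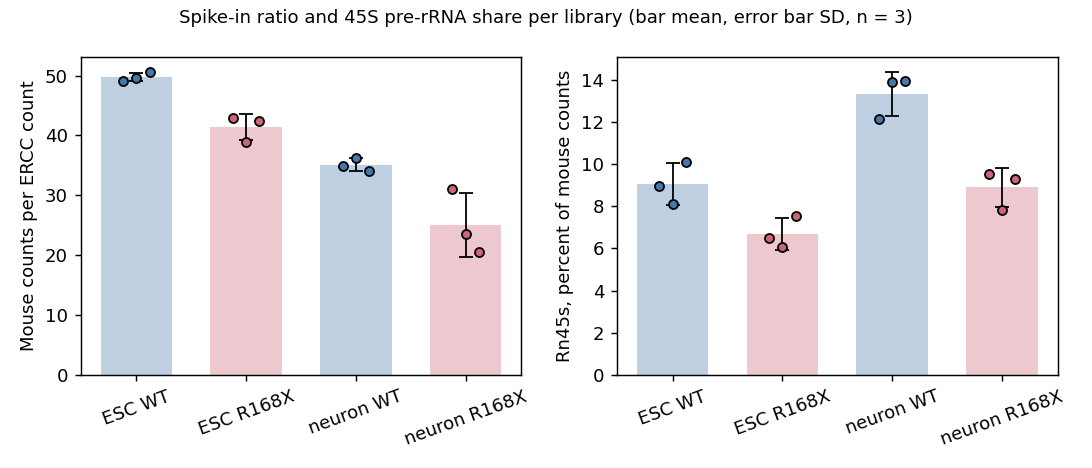
Mouse counts per ERCC count (left) and Rn45s as a percent of mouse counts (right) for the 4 groups. Points are libraries, bars are means and error bars are SD (n = 3), and the R168X means lie below the WT means in both cell types, at 41.4 against 49.7 counts per ERCC count in ESCs.

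In ESCs few genes changed relative to the others, and most changes were under 2-fold. Hunk, a protein kinase gene, fell by 1.08 ± 0.08 (edgeR adjusted p = 2.50e-05), Mb21d2 fell by 0.88 ± 0.08 (edgeR adjusted p = 0.000142) and Bdh1, which encodes a ketone body enzyme, fell by 0.60 ± 0.06 (edgeR adjusted p = 0.000211). Phlda2, an imprinted gene, fell by 1.63 ± 0.21, Fos, an immediate early gene, fell by 1.10 ± 0.18, and Dnmt3l, a cofactor of the de novo DNA methyltransferases, fell by 0.50 ± 0.09. Tagln3, Tbc1d23, Adgrg6, Bbs2, Clec16a and Apod were lower as well, from -1.20 ± 0.17 for Tagln3 to -0.47 ± 0.09 for Apod. Higher were Olig1 (0.95 ± 0.08) and Olig2 (0.73 ± 0.08), which encode transcription factors of the oligodendrocyte lineage, and Stra8 (0.96 ± 0.15), a gene of meiotic entry. Zscan4f, a gene of the 2-cell-like state with near-identical copies and so an uncertain count, was higher by 1.09 ± 0.21. Calb2, which encodes a calcium-binding protein, was higher by 0.79 ± 0.13. Further higher genes were short RNAs or a ribosomal protein gene with pseudogene copies, whose counts are uncertain. They were Snora74a (0.84 ± 0.10), Mir6516 (0.64 ± 0.12), Scarna10 (0.59 ± 0.09) and Rpl39 (0.52 ± 0.06), and the repeat-like Rn4.5s (0.83 ± 0.13) is likewise uncertain. Chromosome 16 carried 13 of the 46 changed genes from 417 tested there, among them Hunk, Mb21d2, Tbc1d23, Bdh1, Clec16a, Apod, Tagln3, Olig1 and Olig2. Chromosome 8 carried 7, among them Bbs2 and Calb2.

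On the relative scale 46 of 13356 ESC genes passed in edgeR's quasi-likelihood test, 24 higher and 22 lower in R168X. DESeq2 called 119, 75 higher and 44 lower, and edgeR without a filter 129, 87 higher and 42 lower. On the spike-in scale 7641 passed, 35 higher and 7606 lower, and 33 genes passed on both scales with the same sign. The spike-in calls share the shift of the median gene by -0.29, because the test takes the scale factors as known. They are therefore not 7641 separate gene results. The relative count was 28 without WT replicate 3, 22, 9 and 133 without R168X replicate 1, 2 and 3, and the spike-in count was 4963 without WT replicate 3 and 4973 without R168X replicate 2. With all 12 libraries in one fit 8 genes passed on the spike-in scale, which ended the calls of Adgrg6, Bbs2, Clec16a, Dnmt3l, Apod and each higher gene named here, while the calls of Calb2, Mir6516, Scarna10 and Rpl39 also ended without single libraries and that of Phlda2 in DESeq2.

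Among the gene groups of ESCs, the 2-cell-like genes lay highest. Over 11 tested members their median was 0.84, and 0.55 on the spike-in scale. Zscan4f alone passed over all genes, 3 members passed adjusted over the list alone, and the family has near-identical copies that make its counts uncertain. The camera adjusted p was 0.000371, and adjusted p = 0.283 with an estimated correlation, while on the spike-in scale it was 0.0254 with an estimated correlation. Ribosomal protein genes had a median of 0.19 over 78 members, 3 of them higher over all genes and 48 adjusted over the list alone, but the median turned to -0.10 on the spike-in scale, where 1 was higher and 10 were lower over all genes and no member passed adjusted over the list alone. The oxidative phosphorylation genes also depended on the scale, with 1 higher of 68 over all genes, 16 adjusted over the list alone and a median of 0.13 that turned to -0.16 on the spike-in scale, where 20 were lower over all genes, 18 adjusted over the list alone, and the rest did not pass. Both lists passed camera (adjusted p = 2.11e-35 and 1.09e-15), and adjusted p = 0.283 with an estimated correlation for each. A trend of relative fold change with transcript length (Spearman -0.161 across genes) was not removed in the list tests. No pluripotency gene passed over all genes on the relative scale in edgeR, but adjusted over the list alone 1 of 27 naive genes, Sall4, and 5 of 16 formative and primed genes, Lefty1, Zic5, Cdh2, Dnmt3b and Zic2, were lower, named after their values were seen. The naive genes had a median of -0.03. On the spike-in scale 21 of the naive genes were lower, among them Utf1 (-0.68 ± 0.10) and Sall4 (-0.50 ± 0.09), with the median at -0.31 beside -0.29 for all genes. Of 39 genes of heterochromatin and DNA methylation 1, Dnmt3l, was lower on the relative scale, and the list passed camera with a median of -0.06 (adjusted p = 0.0147, and 0.283 with an estimated correlation).

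In neurons the genotypes differed widely, and some genes were present in 1 genotype and near absent in the other. Stox1, a winged-helix gene, was at 99.4 ± 6.57 spike-in scaled CPM in WT and 0.326 ± 0.199 in R168X (mean ± SD, n = 3), and Nos1, which encodes the neuronal nitric oxide synthase, at 324 ± 43.9 and 9.12 ± 3.23 CPM. The opposite direction held for Gvin1, at 0.256 ± 0.233 CPM in WT and 155 ± 66.6 in R168X, for Fcrl5, an Fc receptor-like gene, at 0.137 ± 0.190 and 68.6 ± 16.9 CPM, and for Rab17, a small GTPase gene, at 0.113 ± 0.138 and 24.1 ± 3.52 CPM. Slc15a1, a peptide transporter gene, fell by 7.35 ± 0.20 on the log2 relative scale (edgeR adjusted p = 1.16e-08), and Gm13483, Pax6os1, Gm48908 and 9530091C08Rik changed by -7.60 ± 0.24, -7.05 ± 0.32, -6.88 ± 0.20 and -4.68 ± 0.27. Pax6os1 is antisense to Pax6 and its count is uncertain, since the use of strand in counting is not given in the sources used here. Ggnbp1 and Gm4070 were higher by 6.80 ± 0.22 and 6.85 ± 0.71, and the call of Gm4070 ended without WT replicate 2. Foxn1 had 1766 counts in WT and 3 in R168X, a ratio of R168X to WT between 0.000217 and 0.00308 (95% counting interval). In the other direction Cryaa, Gm6117, 4930455B14Rik, Gm7134 and Thbs4 had 1 count and Gm18852 had 2 counts in WT, against 849, 816, 634, 333, 173 and 840 in R168X. The ratio of R168X to WT lay between 94.2 and 20812 for Cryaa, a lens crystallin gene (95% counting interval), between 90.5 and 20004 for Gm6117, between 70.3 and 15548 for 4930455B14Rik, between 36.8 and 8178 for Gm7134 and between 71.9 and 2153 for Gm18852. 1700031L13Rik, with 0 counts in WT, was at least 264-fold higher in R168X. 4933400C23Rik, 1700122H20Rik, B020014A21Rik and 4930555K19Rik, with 0 counts in R168X, were at least 163-fold, 91.95-fold, 89.3-fold and 79.0-fold lower. These bounds take 3 counts over the group as the floor, on the spike-in scale.

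**Figure D2:**
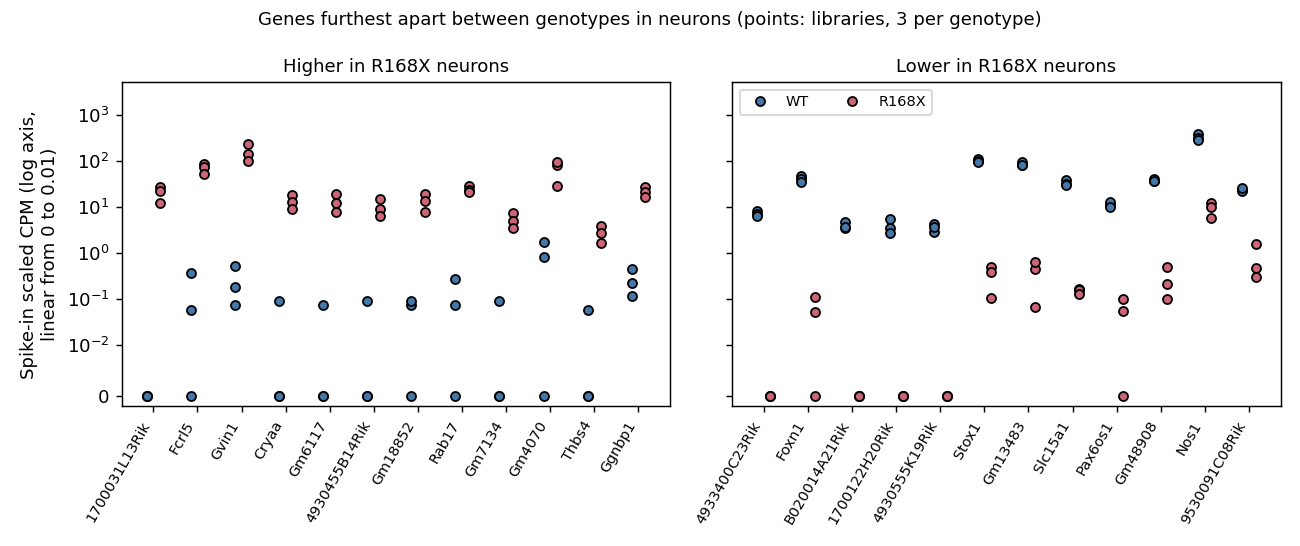
Spike-in scaled CPM (log axis, linear from 0 to 0.01) of the named genes furthest apart between WT and R168X neurons, 1 point per library and 3 libraries per genotype. Stox1 lies at 99.4 CPM on average in WT and 0.326 in R168X, and Gvin1 at 0.256 in WT and 155 in R168X.

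Markers of the cell types around the neurons were lower in R168X. Of 18 fibroblast and mural markers 16 were lower on the relative scale, with a median of -0.58. Col1a1, which encodes a collagen chain, fell by 1.03 ± 0.15 (edgeR adjusted p = 0.000779) and Col3a1 fell by 0.86 ± 0.12. Of 21 astrocyte markers 1 was higher and 16 were lower, with a median of -0.53. Gja1, a gap junction gene of astrocytes, fell by 0.87 ± 0.10 and Aldh1l1 fell by 0.78 ± 0.13. The neurons had been grown on a layer of mouse astrocytes. Both lists passed camera (adjusted p = 2.83e-08 and 0.000102), with adjusted p = 0.465 and 0.570 with an estimated correlation.

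Neurogenic transcription factors, pan-neuronal genes and germline genes were more often higher than lower relative to the other genes, beside the lower astrocyte and fibroblast markers (medians of -0.53 and -0.58). A smaller share of RNA from cells around the neurons would raise neuronal transcripts on this scale without a change in the neurons. The 2 were not tested apart. Of 24 neurogenic transcription factors 15 were higher, with a median of 0.65, and 0.32 on the spike-in scale, where 6 were higher. Neurod1 was higher by 1.40 ± 0.12 and Neurod2 by 1.41 ± 0.12. Neurog2, the factor used to make the neurons, took 3.00 ± 0.0931% of mouse counts in WT and 2.71 ± 0.236% in R168X neurons (mean ± SD, n = 3, exact permutation p = 0.2). Of 30 pan-neuronal genes 18 were higher and 2 lower, with a median of 0.34 that was -0.02 on the spike-in scale, where 1 was higher and 2 were lower. Nsg2, a vesicle protein gene, was higher by 1.17 ± 0.13, and Thy1 fell by 0.52 ± 0.07, though on the spike-in scale the call of Nsg2 ended without WT replicate 1 or 3 and that of Thy1 without R168X replicate 2. Of 26 germline genes silenced by methylation 17 were higher and 1 was lower. Their median was 0.54, and 0.18 on the spike-in scale, where 6 were higher. Sycp1, a gene of the synaptonemal complex, was higher by 2.24 ± 0.21, Dazl, a germ cell RNA-binding protein gene, by 1.34 ± 0.10 and Rpl10l by 1.55 ± 0.13, and Tex19.1 fell by 0.94 ± 0.16. Neurogenic, pan-neuronal and germline lists passed camera (adjusted p = 4.11e-06, 1.38e-05 and 7.03e-06), and the adjusted p was 0.570, 0.388 and 0.527 with an estimated correlation. Of 31 glutamatergic synapse genes 13 were higher and 5 lower, with a median of 0.12 that was -0.17 on the spike-in scale, where 5 were higher and 5 lower, and camera did not call the list on the relative scale (adjusted p = 0.0797). The AMPA receptor subunit gene Gria1 rose by 6.45 ± 0.15, the kainate receptor subunit gene Grik2 by 5.34 ± 0.11 and the vesicular glutamate transporter gene Slc17a7 by 1.79 ± 0.08, while Syngap1 fell by 0.96 ± 0.14. Gria1 and Grik2 were among the 41 neuron genes at least 8-fold apart between genotypes, where line and genotype cannot be told apart. Of 5 tested GABAergic and monoaminergic genes 1 was higher and 1 lower, with a median of -0.26, against 1 higher and 3 lower on the spike-in scale, and camera did not call the list (adjusted p = 0.867). Of 24 genes reported to depend on MeCP2 6 were higher and 7 lower, against 1 higher and 9 lower on the spike-in scale, and camera did not call the list (adjusted p = 0.436).

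Stress and signalling groups were lower, again beside the lower fibroblast and astrocyte markers (medians of -0.58 and -0.53). Interferon-stimulated genes had the lowest median of the lists in neurons, -0.82 over 27 members, 19 of them lower. Oas1a changed by -1.50 ± 0.33 and Xaf1 by -1.42 ± 0.30, and camera gave an adjusted p of 1.25e-07 (adjusted p = 0.533 with an estimated correlation). Of 25 genes of the integrated stress and unfolded protein responses 1 was higher and 12 were lower. Slc7a11, a cystine transporter gene, fell by 1.37 ± 0.10, Asns, the asparagine synthetase gene, fell by 0.82 ± 0.10 and Mthfd2, a mitochondrial folate enzyme gene, fell by 0.82 ± 0.07. Of 22 p53 target genes 1 was higher and 11 were lower, among them Phlda3 (-0.86 ± 0.09) and Sesn2 (-0.81 ± 0.09). Of 20 immediate early genes 2 were higher and 9 lower, Fos at -0.96 ± 0.16 and Egr3 at -0.92 ± 0.26. The stress, p53 and immediate early lists passed camera (adjusted p = 0.00093, 0.00149 and 0.0181), and their adjusted p was 0.620, 0.388 and 0.388 with an estimated correlation. Without R168X replicate 1 the immediate early list was no longer called on the spike-in scale, and with a replicate block the stress list was not called there.

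Over all genes, 5097 of 13838 passed in neurons on the relative scale, 2519 higher and 2578 lower in R168X. On the spike-in scale 3610 passed, 246 higher and 3364 lower, and 2683 passed on both with the same sign. The spike-in count was 1875, 1768 and 1881 without WT replicate 1, 2 and 3, 8755 without R168X replicate 1 and 1297 without R168X replicate 2. Without R168X replicate 3 it was 5005, with 773 higher and 4232 lower, so the number of higher genes rests much on that library. The relative count was 3067 and 3278 without WT replicate 1 and 3 and 3088 without R168X replicate 2.

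The genotype effect of some genes differed between neurons and ESCs when tested directly. Among genes that the naming rule allowed, Rab17, Ggnbp1, Gfra3, Smtnl2 and Rnf207 had the effects that were most positive in neurons against ESCs, and Foxn1, Stox1, Slc15a1, Sgo2b and Igfals those most negative. The difference was 5.36 ± 0.25 for Smtnl2 (edgeR adjusted p = 5.94e-10) and -7.52 ± 0.27 for Slc15a1 (edgeR adjusted p = 1.34e-11) on the log2 spike-in scale. Igfals and Sgo2b lost their call without single libraries. In edgeR 217 of 15077 genes passed on the spike-in scale, 84 with a more positive and 133 with a more negative effect in neurons. On the relative scale 2319 passed, 1066 and 1253. The spike-in count was between 109 and 1766 without single libraries, and each library but ESC R168X replicate 2 moved it more than 1.5-fold. Without neuron R168X replicate 1 the effect was more positive for 178 genes and more negative for 1588. Without neuron R168X replicate 3 these were 1261 and 473, so the balance of directions depends on single libraries. The genotype effects of the cell types went weakly together across 12020 genes, which are not independent replicates (relative scale, Spearman 0.133, Pearson 0.0731). Of 19 genes lower in R168X ESCs and tested in both, 9 were also lower in R168X neurons against 3.30 for independent lists (Fisher's exact p = 0.00244). Of 19 genes higher in R168X ESCs 1 was shared, against 3.47 (Fisher's exact p = 0.231). On the spike-in scale 1576 lower genes were shared, fewer than the 1672 for independent lists (Fisher's exact p = 2.13e-05), and 1 higher gene against 0.192 (Fisher's exact p = 0.175). The shared lower genes of the relative scale were Akap13, Apod, Cbr3, Col18a1, Fos, Nup93, Ogfod1, Tbc1d23 and Vim, and the shared higher genes were Dynlt1b on the relative and Tktl1 on the spike-in scale, all named after the overlap was seen. Apod, Cbr3 and Tbc1d23 lie on chromosome 16 and Nup93 and Ogfod1 on chromosome 8, where the ESC changes crowded. Fisher's exact test treats genes as independent, which limits what its p-values mean. Genotype and line are confounded here, so the overlaps cannot tell a shared genotype effect from a line difference.

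The identity of the neurons was read from WT neurons against WT ESCs. Most naive pluripotency genes were lower in neurons and most pan-neuronal genes higher. Nanog went from 823 ± 41.0 to 0.0522 ± 0.0491 TMM-scaled CPM and Pou5f1 from 693 ± 66.0 to 0.221 ± 0.126 (mean ± SD, n = 3), and the 3 Nanog counts in neurons give a ratio to ESCs between 1.13e-05 and 0.000161 (95% counting interval). Tubb3, a neuronal tubulin gene, went from 77.1 ± 4.31 to 2504 ± 148 CPM, and Dcx, at 0 counts in ESCs, to 902 ± 21.7 CPM, at least 16494-fold more. Of 27 naive pluripotency genes 26 were lower and 1 was higher, and of 30 pan-neuronal genes 29 were higher. Of 16 formative and primed pluripotency genes 4 were higher and 11 lower. The naive and pan-neuronal lists passed camera with an estimated correlation (adjusted p = 0.00278 and 0.0225). The neuron cultures also held markers of other cells. Col1a2, a fibroblast collagen gene, went from 0.877 ± 0.177 to 4270.3 ± 43.2 CPM, 18 of 18 fibroblast and mural markers were higher, and so were 19 of 21 astrocyte markers, among them Slc1a2, at 0 counts in ESCs and 483 ± 11.4 CPM in neurons, at least 8805-fold more. In edgeR 13520 of 15077 genes passed, 6827 higher and 6693 lower in neurons. Cell type and preparation set are confounded here.

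Long genes have been reported to change with MeCP2, so fold change was set against gene span. In ESCs the median relative log2 fold change of the 1611 genes over 100 kb differed from that of the rest by -0.04 (Spearman -0.138 across genes, which are not independent replicates), and it was -0.05 and -0.01 without R168X replicate 1 and 2. In neurons the difference over 2057 such genes was -0.03 (Spearman 0.0150), and it was -0.10 and 0.06 without R168X replicate 1 and 3. With a limit of 50 kb the neuron difference was 0.00394, of the opposite sign.

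The authors' deposited table for ESCs called 6785 genes, 13 higher and 6772 lower in R168X, of which 6629 were shared in direction with the spike-in comparison here. The authors' deposited table for neurons called 3329, 213 higher and 3116 lower, and 3062 were shared. These overlaps compare software on the same libraries.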

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

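The tests on the genes at least 8-fold lower in R168X and on the spread of ESC genes over chromosomes were chosen only after the result was seen. The 8-fold limit and the use of the 2 most crowded chromosomes were set after the data had been explored.

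The genotype effect differed between neurons and ESCs, by a test of the difference itself, for 217 genes on the log2 spike-in scale. Of the named genes Rab17 differed by 7.44, Ggnbp1 differed by 6.59, Gfra3 differed by 5.63, Smtnl2 differed by 5.36, Rnf207 differed by 4.44, Foxn1 differed by -9.35, Stox1 differed by -7.68, Slc15a1 differed by -7.52, Sgo2b differed by -5.23 and Igfals differed by -5.07. Genes near absent in a group have fitted values, which are not bounds. In 100 random splits that shuffled genotype within cell type, the real one included, 9 called as many genes, with 4703 in the highest of the others, so the count does not exclude chance. It is no clean test of chance either, since the other 8 of these kept the true grouping of the neurons and so carry the genotype effect there, and the highest keeps both true groupings with the neuron labels swapped. The 80 splits with neither true grouping called 0 genes in edgeR.

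Gene lists also differed between the cell types in this test, by camera at the preset correlation. The median log2 differences were -1.13 for interferon-stimulated genes, -0.65 for fibroblast and mural markers, -0.57 for astrocyte markers, -0.40 for ribosomal protein genes, -0.36 for integrated stress and unfolded protein response genes, -0.34 for p53 target genes, -0.15 for oxidative phosphorylation genes, 0.54 for pan-neuronal genes, 0.41 for neurogenic transcription factors, 0.35 for methylation-silenced germline genes and 0.26 for glutamatergic synapse genes. With an estimated correlation camera called no list, the lowest adjusted p being 0.736 on the spike-in and 0.194 on the relative scale. On the spike-in scale it also called no list for WT neurons against WT ESCs (lowest camera adjusted p = 0.424). Missing calls on that scale therefore say little. The call of the oxidative phosphorylation genes ended on the relative scale (camera adjusted p = 0.0895) and without ESC WT replicate 1 or neuron R168X replicate 1, and that of the germline genes without neuron R168X replicate 3. Medians over genes near absent in ESCs are fitted values.

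In neurons 41 genes were at least 8-fold apart between genotypes, 23 higher and 18 lower in R168X. Lost repression by truncated MeCP2 would raise the genes it acts on, so it cannot directly account for the 18 lower genes. Indirect effects were not tested. A difference already in the ESCs of the lines is argued against by the 14 genes tested there, with a median log2 fold change signed by the neuron direction of -0.057, though most were too low to test. Local events particular to a line, such as integration of the NGN2 construct, stay open. A share of 56.1% had a neighbour changed the same way, under the random median of 63.4%. That result was set in advance as evidence against local events. However, so many genes changed that events at part of the 41 would not show. An event that acts on a single gene would also leave no changed neighbour, so the share cannot count against such events. Whether the construct was integrated separately in each line is not given in the sources used here. Lost repression stays open for the higher genes as well, whose ESC median of -0.061 over 7 tested genes decides nothing where MeCP2 binding may differ by cell type, while genotype and line cannot be told apart.

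The ESC genes changed on the relative scale crowded on chromosome 16, which held 13 of 46, above 9, the upper end of the central 95% for the most crowded chromosome in random draws. For these single-gene calls a bias by transcript length is argued against, as 93.3% of them stayed past the threshold once the length trend was removed. Such a trend was present, with a Spearman correlation of relative fold change and transcript length of -0.161 before removal and 0.00105 after. The gene lists and the gene-span values were not tested again without it. A copy number change of the whole chromosome in all cells would move most of its genes in the same direction. Of 417 tested genes of chromosome 16 13 changed, 3 higher and 10 lower, and of 718 of chromosome 8 7 changed. The simulated test recovered 79.1% of 1.5-fold changes, so these values argue against such a change. A copy number change of part of a chromosome or in part of the cells, or a sequence difference between the lines, may account for the crowding and stays open. Of 18 such genes of chromosomes 16 and 8 tested in neurons 13 kept their direction, 72.2% with an exact interval of 46.5 to 90.3%, too few to decide. An effect of the genotype was not tested apart from the line.

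Fibroblast and astrocyte markers were lower together in R168X neurons. A smaller share of RNA from the feeder layer may account for this but stays open. Their medians of -0.58 and -0.53 lay close (permutation p = 0.549), which does not show equal falls, as members spread widely (SD 0.243 and 0.485). The 5 most abundant fibroblast markers, among them Col3a1 and Fn1, were all lower. Their falls were uneven, from -1.03 ± 0.15 for Col1a1 to -0.42 ± 0.08 for Fstl1. For the interferon-stimulated genes the median of -0.82 lay below the -0.56 of both marker lists (permutation p = 0.00561). That result was set in advance as evidence against a smaller feeder share. The permutation treats members as independent, though genes of a list can change together, so it does not settle the question. Members spread widely (SD 0.342 and 0.394), which is not the error of a median and was not part of that rule, and Col1a1 changed by -1.03. The genes that passed the count filter in ESCs included 8 of the 18 fibroblast and 10 of the 21 astrocyte markers. They also included 11 of the 27 interferon-stimulated genes. Expression outside the feeder layer may dilute the fall of each of these lists, but expression in the neurons themselves was not measured apart. A lower response in the neurons was not tested.

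Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real ESC split called 7641 genes and the highest other 10, with 1 split as large, the real one. For neurons the real split called 3610 and for the WT libraries of both cell types 13368, again with 1 split as large, and no other split called any gene. On the relative scale another ESC split, of WT replicate 1 with R168X replicates 1 and 2 against the rest, called 332 genes against the real 46, which points to a structure of the ESC libraries beside the genotype.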

How the results depend on the processing

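The alternatives of the relative-scale counts, the ratio without Rn45s and the gene-span values without single libraries were chosen after the data were seen. The global shift and the ratio per ERCC count kept their direction in every alternative run, while the gene-span value of neurons changed sign without R168X replicate 3 and at a limit of 50 kb (0.00394).

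The ESC spike-in count of 7641 was 46 with TMM, 46 with DESeq2 size factors, 119 with the DESeq2 Wald test on mouse size factors and 8 in a fit of all libraries, as the median SE rose from 0.109 to 0.182. Genes shared with the authors' ESC calls were 30, 30, 56 and 7 in that order. The neuron count was 5557 with total ERCC counts. The difference of effects gave 2319 genes with TMM and 456 with DESeq2. The relative ESC count was 129 without a filter (87 higher and 42 lower) and 119 in DESeq2 (75 higher and 44 lower). The scalings set the median gene to no change by construction, and the cause of the other moves was not tested.

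Without single libraries the ESC spike-in count ran from 4963 to 7643, moved by WT replicate 3 (4963) and R168X replicate 2 (4973). Shared ESC calls ran from 4648 to 6333. The neuron count ran from 1297 to 8755, and each library but R168X replicate 3 moved it more than 1.5-fold. Without R168X replicate 3 the higher genes in that count rose from 246 to 773. Shared neuron calls ran from 1270 to 3319, moved by WT replicates 1, 2 and 3 (1825, 1724 and 1814) and R168X replicate 2 (1270). The count of the difference ran from 109 to 1766, moved by each library but ESC R168X replicate 2, with 1766 and 1734 without neuron R168X replicates 1 and 3 and 119, 134, 131, 141, 117, 109, 126, 119, 110 without the others in order. Cell identity ran from 13318 to 13795. Relative counts ran from 9 to 133 in ESCs, moved by WT replicate 3 and each R168X library, and 3067 to 6565 in neurons, moved by WT replicates 1 and 3 and R168X replicate 2, the global shift from -0.32 to -0.23 in ESCs, moved by R168X replicate 2, and -0.52 to -0.23 in neurons, where R168X replicate 3 moved it to -0.23, and the log2 ratio per ERCC count from -0.29 to -0.22 and -0.67 to -0.38. The gene-span difference ran from -0.05 to -0.01 in ESCs and -0.10 to 0.06 in neurons. List counts ran from 8 to 11 in ESCs, 11 to 12 in neurons, 10 to 12 for the difference and 18 to 19 for identity.

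Correlations of same-numbered WT and R168X libraries were 0.191, -0.0261, 0.113, 0.0369, 0.0430, -0.0215, ESCs first. Those of differently numbered ones ran from -0.179 to 0.0987 in ESCs and from -0.0603 to 0.0161 in neurons. The highest value of each cell type was same-numbered, but other same-numbered ones were negative, so whether the numbers pair libraries cannot be told. A replicate block gave 8459 ESC, 4680 neuron, 219 difference and 13541 identity genes, 190 relative ESC (127 higher and 63 lower) and 4771 relative neuron genes, and shifts of -0.29 and -0.37. The block ended the calls of Gm4070, of Igfals and of the ribosomal protein and stress response lists in neurons on the spike-in scale, and changed no other call of a named neuron gene or list to past or under the threshold.

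ESC log2 fold changes of Fbln1, Hexb, Rpl18a, Rpl7a, Rpl29 and Rps9 turned from negative to 0.00248, 0.0045, 0.0185, 0.0288, 0.0503, 0.052 with TMM, 0.00218, 0.00432, 0.0183, 0.0285, 0.0498, 0.0516 with DESeq2 size factors and 0.00286, 0.00502, 0.0192, 0.0294, 0.0508, 0.0526 in DESeq2 on mouse size factors. Of 1652 values under alternatives of named ESC genes 508 kept their direction but lost their call, beside the 18 that turned, of 1722 in neurons 181 and of 176 for the difference 9. With TMM the spike-in call ended for the naive pluripotency and ribosome biogenesis lists in ESCs, the glutamatergic list in neurons and the oxidative phosphorylation list for the difference. Depth limits genes at few counts, and the simulated test found fewer of the 1.5-fold than of the 2-fold changes.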

Other observations

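Members of further lists changed in R168X neurons on the relative scale, and of these lists camera called the ribosomal protein and mesendoderm genes, beside the lower fibroblast and astrocyte markers (medians of -0.58 and -0.53). Of 37 imprinted genes 11 were higher and 12 lower, with Slc38a4, an amino acid transporter gene, at 1.51 ± 0.14 and the growth factor gene Igf2 at -0.72 ± 0.11, and camera did not call the list (adjusted p = 0.867). Of 78 ribosomal protein genes 1 was higher and 13 were lower, among them Rpl22 (-0.86 ± 0.09) and Rps12 (-0.64 ± 0.14). That list passed camera (adjusted p = 0.00420, and 0.911 with an estimated correlation), though on the spike-in scale a replicate block ended its call. Of 9 mesendoderm genes 5 were lower, among them Lama1 (-0.90 ± 0.16) and Dab2 (-0.70 ± 0.13), and the list passed camera on the relative scale (adjusted p = 0.0155, and 0.514 with an estimated correlation). Of 32 proliferation genes 4 were higher and 6 lower (camera adjusted p = 0.762), and Rrm1, which encodes a subunit of ribonucleotide reductase, fell by 1.45 ± 0.08 (edgeR adjusted p = 3.28e-06). Of 30 axon growth and guidance genes 8 were higher and 10 lower (camera adjusted p = 0.889), with Chl1, a cell adhesion gene, at -0.93 ± 0.15 and the netrin receptor gene Unc5b at -0.73 ± 0.09. Of the naive pluripotency list Esrrb (-1.06 ± 0.11) and Lin28a (-1.51 ± 0.19) were lower in neurons, while of 16 members 2 were higher and 4 lower (camera adjusted p = 0.235). Which cells of the cultures these transcripts came from was not tested. Cldn11 and Pdgfra, listed as oligodendrocyte lineage markers, changed by -1.18 ± 0.12 and -1.20 ± 0.10, and camera did not call that list (adjusted p = 0.436). With spike-in scaling 2 imprinted genes were higher and 12 lower, 1 axon gene was higher and 10 lower, and 42 ribosomal protein, 6 proliferation and 7 naive pluripotency genes were lower.

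In ESCs the germline list was higher relative to other genes without any member passing in edgeR on its own, with a median of 0.15 over 24 members that was -0.13 on the spike-in scale (camera adjusted p = 0.0117, and 0.283 with an estimated correlation). The formative and primed pluripotency list had a median of -0.09 over 16 members (camera adjusted p = 0.00926, and 0.283 with an estimated correlation). Lefty1, a Nodal antagonist gene, was at -0.30 ± 0.07 and Zic5 at -0.33 ± 0.09, neither past the threshold over all genes (edgeR adjusted p = 0.106 and 0.141).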
